A study of Mus musculus with 10 samples.

How the data were processed

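The series holds 10 libraries of total RNA from epididymal white adipose tissue, the visceral fat depot that lies against the epididymis, of male C57BL/6 mice. The animals were 18 weeks old and had been kept for 8 weeks on a diet rich in sucrose and fat. Of the 10 mice, 5 were wild-type (Srgn+/+) and 5 lacked serglycin (Srgn-/-), here called Srgn-knockout. Each library comes from a separate animal, so the p-values measure the spread between these animals. Samples are named by group and by their order within it, which pairs no animal of 1 group with an animal of the other.

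Libraries were made with the Ion AmpliSeq mouse transcriptome kit, which amplifies 1 short target (amplicon) per gene, and were read on an Ion S5 XL sequencer. The processing notes name genome build mm9, while the aligner and the read counter are not given in the sources used here. The position of the Srgn amplicon relative to the deleted part of the gene is not given either. The authors deposited a table of raw counts, which holds whole-number reads for 23930 amplicons in each library. The authors also deposited a table of reads-per-million values (RPM). Each RPM value equals the raw count scaled by the total of its column, with a largest difference of 0.00059109, so this table corrects for total reads and for nothing else. Because each gene is read at 1 amplicon, gene length does not enter the counts, but differences between amplicons in efficiency do, and levels of different genes are not compared. AmpliSeq reads are PCR products without molecular identifiers, so floors cover counting error only. A floor is the level that 3 reads would give in a library. The reference annotation at hand was of assembly GRCm38, another build than that of the files, and was used only for which genes neighbour each other; no coordinates are given.

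Total counts were 10221220, 10757779, 9837689, 9212223 and 7824764 reads in wild-type 1 to 5 and 10128049, 8595791, 8239716, 8176075 and 8989727 in Srgn-knockout 1 to 5. The raw counts were analysed in R 4.3.3. Genes were kept by the default filter of edgeR 4.0.16 (filterByExpr, minimum count 10 and minimum total count 15), which left 12719 genes to test and removed 11211. Libraries were scaled by trimmed mean of M-values (TMM) factors, and the groups were compared by the edgeR quasi-likelihood test with robust dispersion, two-sided, with no covariate. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are normalized counts-per-million (CPM) values given as mean ± SD over 5 libraries; levels of epididymis, testis and seminal vesicle genes in single libraries, of Gpr50, and the shares given for Mtrf1 and Tdrd3 are CPM without TMM factors. Fold changes are log2 of Srgn-knockout over wild-type with their standard error (SE). The median SE over the tested genes was 0.165.

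The groups, the test, the filter, 32 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names Srgn and, in each direction, the 12 genes with the smallest p and the 3 with the largest change among genes past the threshold with a mean CPM of at least 1 and a gene symbol that is not a predicted or clone name. Where no gene passes in a direction, it names the 5 with the smallest p as not past the threshold. In each list described it names up to 4 tested members with the smallest p, whether or not they pass. Genes outside this rule are named as chosen after their values were seen.

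Of the 643 genes on the lists, counted once, 521 were tested. The lists cover immune cells (macrophages, lipid-associated macrophages, T cells, B cells, NK and cytotoxic granules, mast cells, neutrophils, dendritic cells and MHC class II), immune programmes (alternative activation and type 2 immunity, inflammatory cytokines and chemokines, interferon response, complement), and adipocyte metabolism (adipocytes, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, oxidative phosphorylation, thermogenic adipocytes, insulin signalling and glucose handling). Others cover the stroma (extracellular matrix and fibrosis, proteoglycans and glycosaminoglycan synthesis, adipose progenitors and fibroblasts, endothelial cells), other tissues (mesothelial cells, epididymis and testis, skeletal and smooth muscle, blood), cell state (immediate early and stress, unfolded protein response, cell cycle, circadian clock) and the neighbours of Srgn on chromosome 10. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 32 lists. The same lists were tested with the correlation estimated from the data, with fry, and with an exact permutation test of each library's list mean. Fry was run in a directional form and in a mixed form, which takes changes of members in either direction. Values of fry are of the directional form unless named as mixed. The list mean of a library is the mean of its members' log2 CPM, centred per gene over the 10 libraries. For 5 against 5 libraries the smallest p an exact two-sided permutation test can give is 0.00794. A second list of epididymis genes and a list of seminal vesicle genes were written later, before the values of their members were looked at.

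Alternatives were DESeq2 size factors, upper-quartile factors and library size alone in the edgeR fit, and the DESeq2 1.42.0 Wald test. Further alternatives were limma-voom with quality weights, limma-trend on the authors' values (log2 of the value plus 1), no low-count filter, a CPM of at least 5 in at least 5 samples, and 2 other thresholds (an adjusted p under 0.1, and an absolute log2 change of at least 1 added). The total count or 1 surrogate variable (sva 3.50.0) was also used as a covariate, and each library was left out in turn. The fit without the 3 libraries with the most epididymis RNA, the exact permutation test of list means and the use of members of at least 5 CPM alone were chosen after seeing the data. That fit leaves out wild-type 4 and Srgn-knockout 3 and 5. A call lost in it can come from fewer animals, or from other traits of these animals, as well as from less epididymis RNA.

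The pipeline was tested on simulated data of this design with 12555 genes, of which 215 changed. The edgeR test recovered 26.9% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 97.0% of those changed 4-fold, with 11 false calls among 137. The DESeq2 Wald test recovered 41.8%, 79.1% and 98.5% at these sizes, with 39 false calls among 190. Camera with either correlation and fry called the 1 changed list and none of 30 unchanged lists; the simulation gave genes no shared variation.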

Results

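Gene expression was measured in epididymal white adipose tissue of 10 male mice on a diet rich in sucrose and fat, 5 wild-type and 5 Srgn-knockout. Srgn encodes serglycin, a proteoglycan stored in the secretory granules of mast cells, cytotoxic lymphocytes and other blood-derived cells. The 10 libraries held 7824764 to 10757779 reads each, with means of 9570735 ± 1126989 in wild-type and 8825872 ± 797067 in Srgn-knockout (SD, n = 5; two-sided exact permutation p = 0.270). Between 16850 and 18638 amplicons had at least 1 read in a library. The 10 genes with the most reads took 9.90% to 13.6% of each library, and Scd1, a fatty acid desaturase, took the most in every library.

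The comparison of the genotypes asks what the loss of serglycin changes in diet-fed visceral fat, in particular in its immune profile. Srgn fell to 0.319% of its wild-type level in Srgn-knockout fat and was the sole gene past the threshold in edgeR. At the same threshold the DESeq2 Wald test called 114 genes higher and 107 lower, and limma-voom 2 and 8. Genes of B cells and T cells fell as groups in camera, to a geometric mean of 0.602 and 0.571 of the wild-type level. Genes of NK cells and macrophages fell too, but those calls depended on single libraries. Among these lists, only the B-cell list means did not overlap between the groups. These calls of camera rest on a preset correlation between genes. With an estimated correlation 0 lists passed in camera, with adjusted p = 0.0911 for B cells, 0.838 for T cells, 0.897 for NK cells and 0.898 for macrophages. At the preset correlation camera called at least 4 lists in 79 of 100 splits of the libraries, the real one included. Gene groups of adipocytes, fatty acid metabolism, mitochondria and extracellular matrix did not pass the test in either direction. RNA typical of the epididymis was present in a few libraries of both genotypes.

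The Srgn amplicon had 776, 1047, 1301, 851 and 1005 reads in wild-type 1 to 5 and 3, 1, 0, 0 and 12 reads in Srgn-knockout 1 to 5. Its normalized level was 108 ± 25 CPM in wild-type and 0.343 ± 0.555 CPM in Srgn-knockout (SD, n = 5), a log2 fold change of -8.18 (SE 0.508; edgeR adjusted p = 9.44e-05). Every Srgn-knockout library lay below every wild-type library. The 0 reads in Srgn-knockout 3 and 4 allow levels of up to 0.357 and 0.383 CPM, the level of 3 reads. Srgn-knockout 5 held 12 of the 16 Srgn reads of its group, and without it the log2 fold change was -9.74.

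**Figure D1:**
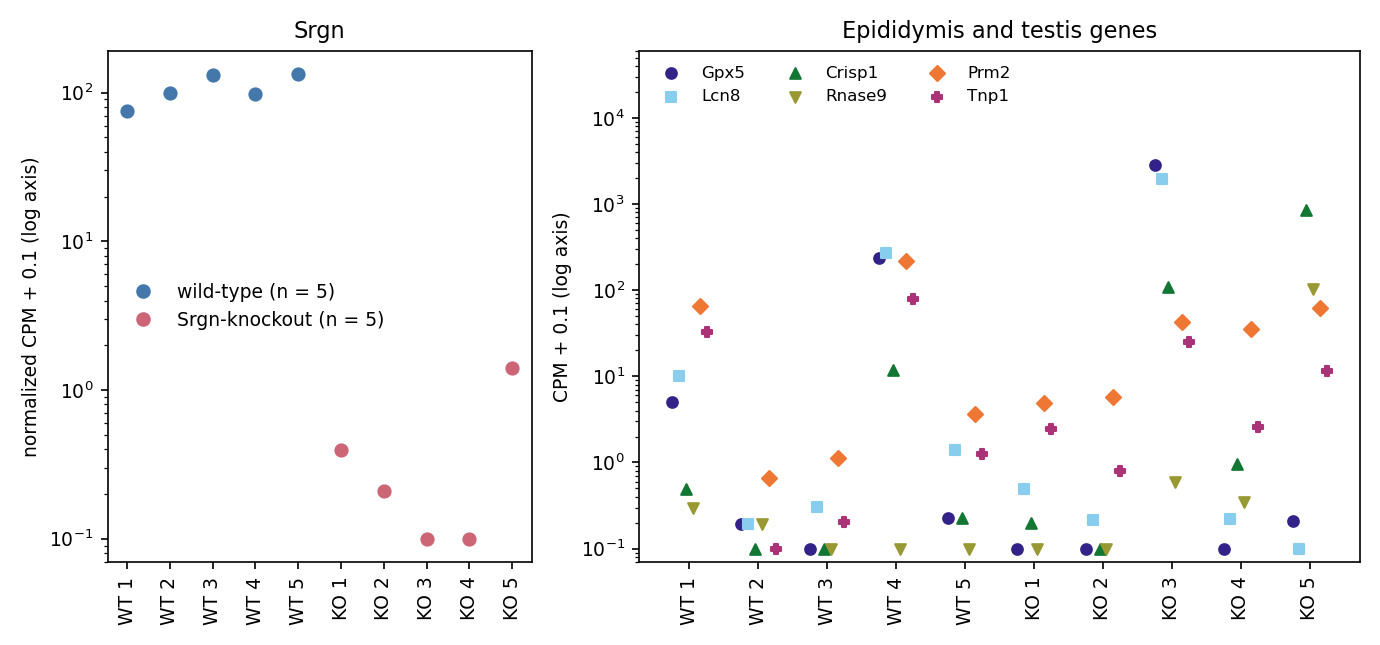
Left, normalized CPM of Srgn plus 0.1 on a log axis in each library, with wild-type (n = 5) in blue and Srgn-knockout (n = 5) in red; all Srgn-knockout libraries lie at or below 1.31 CPM. Right, CPM without TMM factors plus 0.1 on a log axis of 4 epididymis genes (Gpx5, Lcn8, Crisp1, Rnase9) and 2 testis genes (Prm2, Tnp1) in each library, with Gpx5 highest in Srgn-knockout 3 (2811 CPM) and Crisp1 highest in Srgn-knockout 5 (846 CPM).

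Beyond Srgn, 0 genes rose and 0 fell by the edgeR quasi-likelihood test, and the next smallest adjusted p was 0.109. At an unadjusted p under 0.05 there were 1632 genes, 861 higher and 771 lower in Srgn-knockout, where chance would give about 636. With limma-voom there were 2653 such genes. Without the 3 libraries with the most epididymis RNA, an alternative chosen after seeing the data, there were 540, where chance would give about 647. That fit leaves out wild-type 4 and Srgn-knockout 3 and 5. Fewer animals and less epididymis RNA cannot be told apart as reasons for the smaller number. The DESeq2 Wald test called 114 genes higher and 107 lower, limma-voom with quality weights called 2 and 8, and limma-trend on the authors' values called 0 and 1. The groups did not overlap for 353 genes (2.78%), against 0.794% by chance for each gene taken alone. Genes vary together over libraries, and this count was not made for other splits of the libraries. Whether 353 exceeds what other splits give is therefore not known. At least 1632 genes at an unadjusted p under 0.05 in edgeR came in 8 of 100 splits, the real one included. The 5 genes with the smallest p among those with higher values were not past the threshold in edgeR. Some passed under alternatives, among them Minos1 and Ctcflos with limma-voom and with 1 surrogate variable, and Mccc2 with 1 surrogate variable. The genes that passed in DESeq2 or with 1 surrogate variable are not all named here, so other named genes may have passed in these too. Minos1, a subunit of the mitochondrial inner membrane organizing complex, had 78.4 ± 4.90 CPM in wild-type and 107.9 ± 2.44 CPM in Srgn-knockout (log2 0.46, SE 0.0726, edgeR adjusted p = 0.109). Ctcflos, a noncoding RNA gene, had 57.7 ± 4.42 and 86.1 ± 10.6 CPM (log2 0.58, edgeR adjusted p = 0.152). Pcdh17, a protocadherin, had 3.41 ± 0.675 and 7.77 ± 1.92 CPM, Mccc2, an enzyme of leucine breakdown, 32.8 ± 4.10 and 51.5 ± 9.12 CPM, and Tdrd3, a Tudor-domain protein, 17.7 ± 5.70 and 35.8 ± 3.16 CPM (edgeR adjusted p = 0.191 each). Tdrd3 had 8.09 CPM in wild-type 5 and 17.0 to 22.1 CPM in the other wild-type libraries. Every wild-type library lay below every Srgn-knockout library for Tdrd3. A difference in genetic background between the animals stays open for it and could not be told apart from the genotype. Lower values not past the threshold in edgeR included Gemin8, of the complex that assembles spliceosomal particles, at 4.86 ± 2.12 and 0.633 ± 0.399 CPM (log2 -2.90). They also included Rmrp, the RNA of the RNase MRP enzyme, at 6165 ± 945 and 3508 ± 256 CPM (log2 -0.81; edgeR adjusted p = 0.109 for both). The MHC class I genes H2-D1 (log2 -0.64) and H2-T22 (log2 -0.57) had adjusted p = 0.191 in edgeR; related class I genes are close in sequence, and how specific each amplicon is was not tested. Gemin8, Rmrp, H2-D1 and H2-T22 were chosen after their values were seen. Gemin8 and Rmrp passed with limma-voom and with no low-count filter. Gemin8, H2-D1 and H2-T22 were among the genes that passed with 1 surrogate variable.

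B-cell genes fell as a group (camera adjusted p = 1.16e-05; adjusted p = 0.0911 with an estimated correlation). Of 15 tested members, 14 had lower values in Srgn-knockout, with a median log2 fold change of -0.71, and the 5 Srgn-knockout libraries all had a lower list mean than the 5 wild-type libraries (exact permutation p = 0.00794, adjusted p = 0.254 over the 32 lists). No member passed over all genes in edgeR without a covariate, and 3 fell when adjusted over the list alone. These were Pou2af1, a transcriptional coactivator of B cells, at 8.29 ± 3.28 and 3.09 ± 1.0 CPM (log2 -1.43), Cd79b of the B-cell receptor at 8.30 ± 2.15 and 4.83 ± 0.764 CPM (log2 -0.78), and Jchain, which joins secreted immunoglobulins, at 47.7 ± 37.4 and 12 ± 6.14 CPM (log2 -1.99, and -1.39 without wild-type 2). Fcmr, the IgM receptor, had 3.24 ± 1.11 and 1.20 ± 1.08 CPM (log2 -1.44, and -2.04 without Srgn-knockout 3) and did not pass.

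T-cell genes also fell as a group (camera adjusted p = 1.16e-05; adjusted p = 0.838 with an estimated correlation), with a median log2 fold change of -0.97 and lower values for 13 of 14 tested members. The list mean differed by -0.81 on the log2 scale (exact permutation p = 0.0238, adjusted p = 0.381). It was highest in wild-type 3 (1.28) and wild-type 2 (0.71), while wild-type 1 and 4 (-0.065 each) lay below Srgn-knockout 3 (0.002). Adjusted over the list alone, 3 members fell. Cd2, a T-cell adhesion receptor, had 15.1 ± 1.92 and 9.23 ± 1.77 CPM (log2 -0.71), and the chains of the CD8 coreceptor had 2.96 ± 1.94 and 0.709 ± 0.590 CPM for Cd8b1 (log2 -2.06, and -3.07 without the 3 epididymis libraries) and 2.97 ± 2.0 and 0.837 ± 0.704 CPM for Cd8a (log2 -1.83, and -2.43 without Srgn-knockout 3). Cd4, at 2.58 ± 1.63 and 1.10 ± 0.431 CPM, did not pass. Many of these lymphocyte genes lie near 1 to 10 CPM, so that counting error is a larger part of their spread. Only 4 T-cell members and 4 NK members had a mean of at least 5 CPM, under the minimum of 5 members for a test, so these 2 calls could not be tested without the genes of low level. With members of at least 5 CPM alone, an alternative chosen after seeing the data, the B-cell list (8 members, camera adjusted p = 0.00185) and the macrophage list (16 members, 0.0201) still passed.

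NK and cytotoxic granule genes fell as a group (camera adjusted p = 0.0103; adjusted p = 0.897 with an estimated correlation; exact permutation p = 0.0635), with a median log2 fold change of -0.66 and lower values for 7 of 8 tested members. The examples Ctsw (6.55 ± 1.72 and 4.07 ± 0.807 CPM), Nkg7 (7.04 ± 4.02 and 3.69 ± 1.02 CPM), Il2rb (12 ± 7.70 and 6.46 ± 1.75 CPM) and Prf1, the pore-forming perforin (2.65 ± 1.07 and 1.71 ± 0.621 CPM), did not pass on their own. The member with a higher value, Klrb1c (log2 1.81), chosen after its values were seen, reached 189 CPM in Srgn-knockout 3 and 28.5 CPM in wild-type 4, which also held epididymis RNA, and no more than 9.64 CPM in the other libraries; without Srgn-knockout 3 its log2 was -1.97.

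Macrophage genes fell as a group (camera adjusted p = 0.0103; adjusted p = 0.898 with an estimated correlation; exact permutation p = 0.325), with a median log2 fold change of -0.42 and lower values for 18 of 19 tested members. Their values included Lyz2, the macrophage lysozyme (2159 ± 771 and 1341 ± 328 CPM), the complement component C1qc (21.1 ± 8.35 and 13.2 ± 4.12 CPM), the endotoxin coreceptor Cd14 (94.7 ± 33.5 and 61.0 ± 21.8 CPM) and Aif1 (43.0 ± 14.4 and 28.0 ± 10.6 CPM), none past the threshold. Wild-type 1 had a macrophage list mean of -0.84, while the other wild-type libraries lay between 0.21 and 0.79. Lipid-associated macrophage genes, which mark macrophages around dying fat cells, had a median log2 fold change of -0.49 and did not pass (camera adjusted p = 0.149). Among them were Acp5 (343 ± 7.08 and 410 ± 52.9 CPM), Cd9 (212 ± 81.1 and 156 ± 12.8 CPM), Slamf9 (41.3 ± 12 and 27.6 ± 11.3 CPM) and the lysosomal protease Ctsd (6363 ± 2029 and 4842 ± 1258 CPM).

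Both macrophage and NK calls depended on single libraries. The macrophage list had camera adjusted p = 0.103 without wild-type 3, 0.143 without wild-type 5, 0.127 without Srgn-knockout 2 and 0.0766 without Srgn-knockout 3. It had 0.230 without the 3 libraries with the most epididymis RNA, an alternative chosen after seeing the data that also leaves fewer animals. The NK list had camera adjusted p = 0.0689 without wild-type 2, 0.103 without wild-type 3 and 0.0653 without Srgn-knockout 4. Over the 32 lists, 4 were lower and 0 higher in camera with the preset correlation, and 0 passed with the estimated correlation. Directional fry passed 1 list (B cells), and the exact permutation test passed 0. Mixed fry passed 3 lists, B cells (adjusted p = 0.00557), mast cells (0.0333) and T cells (0.0414).

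**Figure D2:**
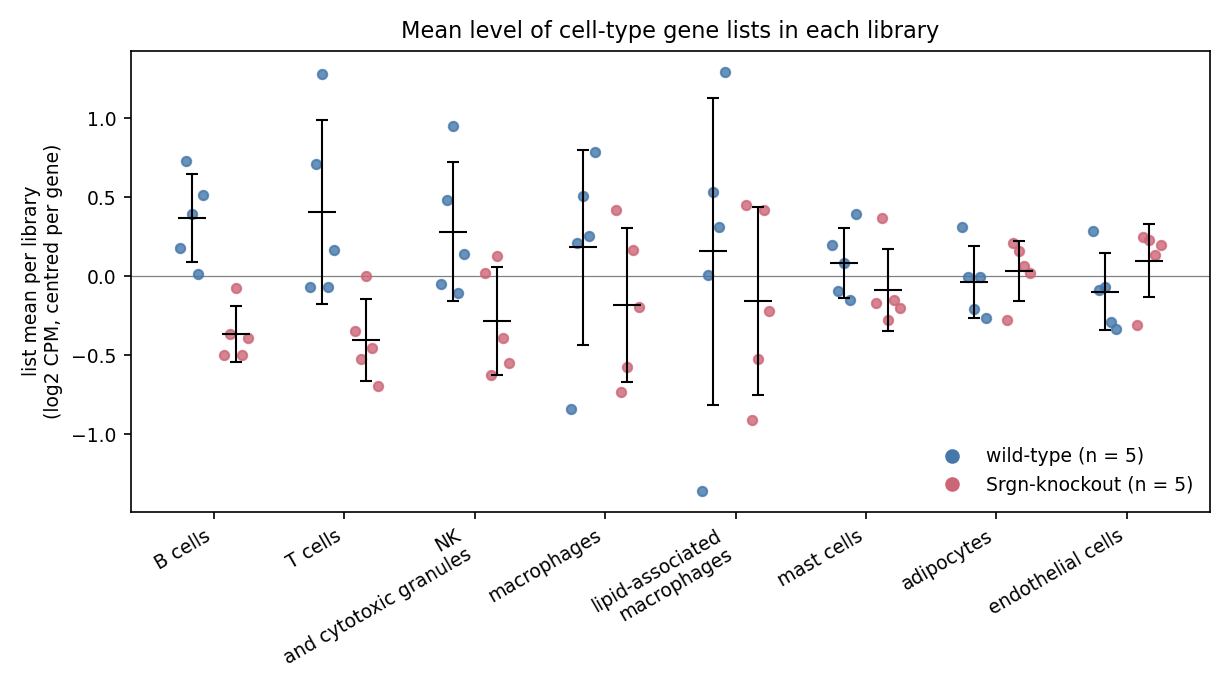
List mean per library (log2 CPM centred per gene) for 8 cell-type lists, with wild-type in blue and Srgn-knockout in red (n = 5 each); points are libraries, and bars give the mean and SD. The B-cell means of the groups do not overlap, while those of the lipid-associated macrophage list span -1.36 to 1.29 within wild-type.

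Other immune groups did not pass in camera. Dendritic cell and MHC class II genes had a median log2 fold change of -0.26 (camera adjusted p = 0.0684), with Ccr7, a migration receptor, at 5.10 ± 1.83 and 2.58 ± 0.703 CPM, Clec9a at 8.12 ± 1.69 and 5.27 ± 0.939 CPM, the class II transactivator Ciita at 59.6 ± 16.8 and 40.7 ± 14.3 CPM, and H2-Ab1 at 1144 ± 306 and 822 ± 237 CPM. This list passed in camera, lower in Srgn-knockout, under 7 alternatives that kept all libraries, among them upper-quartile factors (adjusted p = 0.0284), limma-voom (0.00219) and no filter (0.0362), but not without the 3 epididymis libraries (0.230). Inflammatory cytokines and chemokines had a median of -0.35 (adjusted p = 0.101), with the B-cell chemoattractant Cxcl13 at 17.3 ± 25.4 and 4.14 ± 1.18 CPM (log2 -2.07, and -0.52 without wild-type 2), Cxcl2 at 2.66 ± 0.338 and 1.72 ± 0.719 CPM, Nos2 at 6.95 ± 2.12 and 9.10 ± 1.94 CPM, and Cxcl9 at 124 ± 87.3 and 80.5 ± 10.5 CPM; they passed with upper-quartile factors (adjusted p = 0.0427) and with limma-voom (0.00760). Mast cells store much serglycin. Their list passed in mixed fry (adjusted p = 0.0333) but not in directional fry (adjusted p = 0.842) or in camera. Of the 10 tested mast-cell genes (median -0.20, camera adjusted p = 0.478), 1 rose and 1 fell when adjusted over the list alone, Gata2, a transcription factor shared with other cells (7.57 ± 0.795 and 13 ± 2.82 CPM, log2 0.77), and the tryptase Tpsb2 (38.4 ± 9.05 and 22.5 ± 5.45 CPM, log2 -0.77). The chymases Mcpt4 (15.1 ± 4.48 CPM in wild-type, log2 -0.58) and Cma1 (14.7 ± 3.38 and 12.5 ± 2.43 CPM) did not pass; tryptase and chymase genes each have close relatives, and amplicon specificity was not tested. Neutrophil genes had a median of -0.34 (adjusted p = 0.893), and their member Lcn2, chosen after its values were seen, reached 579 CPM in Srgn-knockout 3, against 25.1 to 87.1 CPM elsewhere (log2 1.90, and 0.54 without that library). Alternative activation and type 2 immunity did not pass in camera (median 0.14, adjusted p = 0.478), but its member Retnla, a secreted marker of alternatively activated macrophages chosen after its values were seen, rose when adjusted over the list alone (986 ± 231 and 1554 ± 314 CPM, log2 0.66, adjusted p = 0.0460 over the list and 0.225 over all genes in edgeR). The interferon response (median -0.15, adjusted p = 0.202) and complement (median -0.24, adjusted p = 0.532) did not pass in camera either.

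The lists of fat-cell genes did not pass the test. The adipocyte list had a median log2 fold change of -0.03 and a mean of 0.05, which differ in sign (camera upward, adjusted p = 0.646). Its members with the smallest p were the fatty acid transporter Cd36 (1535 ± 226 and 1892 ± 86.7 CPM), the retinol carrier Rbp4 (903 ± 131 and 1152 ± 233 CPM), Retn, which encodes resistin (831 ± 457 and 1268 ± 481 CPM), and Car3 (12854 ± 5043 and 16086 ± 5863 CPM), and none passed. In fatty acid and triglyceride synthesis (median 0.05, adjusted p = 0.202), 18 of 22 members had higher values and 1 rose when adjusted over the list alone, Pnpla3, a lipid-droplet protein (442 ± 48.0 and 706 ± 191 CPM, log2 0.67). The desaturase Fads2 (25.1 ± 5.49 and 41.3 ± 17.1 CPM), Acaca, the enzyme that makes malonyl-CoA (28.9 ± 6.54 and 41.3 ± 10.9 CPM), and Agpat2 (1269 ± 133 and 1439 ± 202 CPM) did not pass. Without Srgn-knockout 1 this list (adjusted p = 0.0316) and the thermogenic list (0.0480) passed in camera as higher. Thermogenic adipocyte genes had a median of 0.21 (adjusted p = 0.202), and Slc27a2, a fatty acid transport protein, rose when adjusted over the list alone (2.09 ± 0.732 and 5.53 ± 2.97 CPM, log2 1.40). Cox7a1 (4.3 ± 1.31 and 6.34 ± 1.39 CPM), Cox8b (63.1 ± 22.7 and 96.7 ± 46.5 CPM) and the coactivator Ppargc1a (6.22 ± 2.19 and 8.09 ± 2.05 CPM) did not. Cholesterol synthesis (median 0.01, adjusted p = 0.646), fatty acid oxidation (median 0.01, adjusted p = 0.646), oxidative phosphorylation (median 0.01, adjusted p = 0.646) and insulin signalling (median -0.06, adjusted p = 0.478) did not pass in camera.

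Endothelial genes had higher values for 11 of 15 members (median 0.20, camera adjusted p = 0.0684), with Egfl7 at 53.2 ± 9.62 and 71.6 ± 12.4 CPM, the VEGF receptor Kdr at 39.9 ± 14.4 and 65.1 ± 16.9 CPM, Cdh5 at 153 ± 34.8 and 204 ± 40.01 CPM, and Pecam1 at 311 ± 18.0 and 357 ± 36.0 CPM. The list passed as higher with limma-voom (adjusted p = 0.000483), no filter (0.0267) and the stricter filter (0.0454), but not without the 3 epididymis libraries (0.709). In extracellular matrix and fibrosis (median 0.01, adjusted p = 0.646), Thbs1, the matricellular protein thrombospondin, fell when adjusted over the list alone (719 ± 265 and 314 ± 119 CPM, log2 -1.20). The collagens Col1a2 (511 ± 123 and 686 ± 19.8 CPM) and Col5a2 (215 ± 28.5 and 175 ± 24.9 CPM) and Sparc (5677 ± 812 and 7359 ± 753 CPM) did not pass. In the unfolded protein response (median -0.10, adjusted p = 0.202), the chaperone Hsp90b1 fell when adjusted over the list alone (781 ± 104 and 570 ± 52.9 CPM, log2 -0.45), while the stress sensor Ern1 (20.6 ± 1.55 and 25.8 ± 2.80 CPM), Pdia4 (187 ± 21.6 and 157 ± 15.3 CPM) and Sdf2l1 (86.8 ± 29.2 and 58.9 ± 13.2 CPM) did not pass. Over all lists, 14 members passed when adjusted over the list alone, 9 of them lower, and 0 passed over all genes in edgeR without a covariate. With 1 surrogate variable, Cd2 and Kdr were among the genes that passed over all genes.

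Genes flanking Srgn on chromosome 10 did not shift as a group (median 0.03, camera adjusted p = 0.646). Their members Slc25a16 (23.5 ± 5.22 and 30.9 ± 2.58 CPM), Kif1bp (68.1 ± 12.1 and 55.9 ± 6.48 CPM), Hk1 (28.7 ± 4.80 and 23.7 ± 2.45 CPM) and Tspan15 (27.0 ± 6.36 and 33.7 ± 5.48 CPM) did not pass. Within 10 Mb of Srgn, 7 of 73 tested genes had an unadjusted p under 0.05 (9.59%), against 1560 of 12094 elsewhere (12.9%; odds ratio 0.716, 95% interval 0.277 to 1.56, Fisher's exact p = 0.486).

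Proteoglycans and glycosaminoglycan synthesis did not pass in camera (median log2 fold change -0.13, adjusted p = 0.646). Its member Gpc4, a glypican with heparan sulphate chains chosen after its values were seen, rose when adjusted over the list alone (9.75 ± 1.97 and 16.4 ± 2.5 CPM, log2 0.74, adjusted p = 0.0226 over the list and 0.191 over all genes in edgeR), and the groups did not overlap. The remaining lists did not pass in camera either. These were adipose progenitors and fibroblasts (median 0.09, adjusted p = 0.518), mesothelial cells (-0.10, adjusted p = 0.663), skeletal and smooth muscle (0.21, adjusted p = 0.202), and blood (0.28, adjusted p = 0.824). Immediate early and stress genes had a median of -0.13 (adjusted p = 0.202), the cell cycle -0.07 (adjusted p = 0.928) and the circadian clock -0.05 with an upward test (adjusted p = 0.824).

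**Figure D3:**
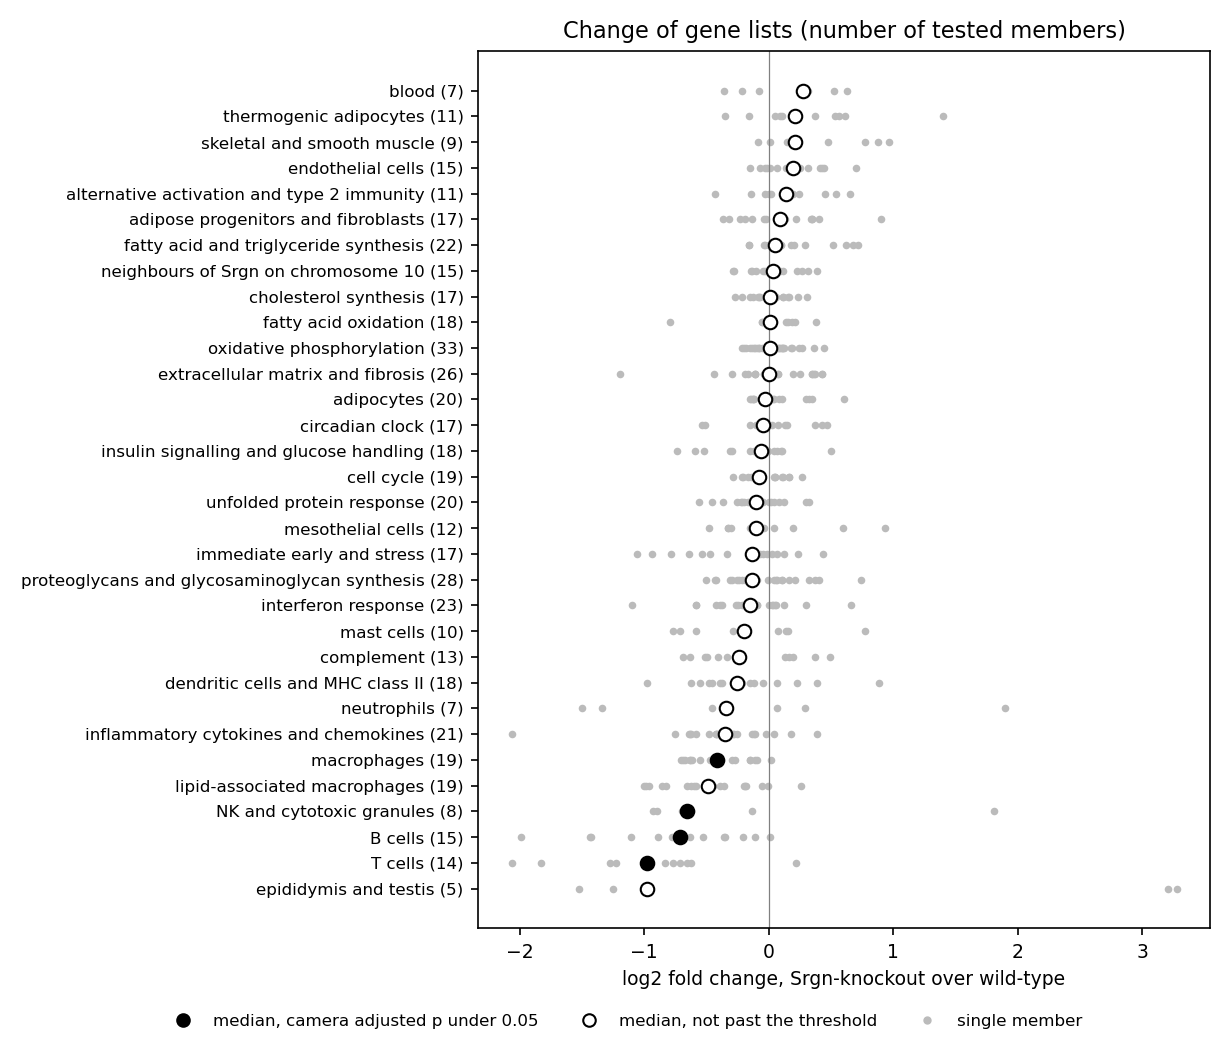
Log2 fold change of Srgn-knockout over wild-type for each of the 32 lists, with the number of tested members in brackets; grey points are members, large points the list median, filled where the camera adjusted p is under 0.05. The 4 filled medians, of T cells, B cells, NK and cytotoxic granules and macrophages, lie between -0.97 and -0.42.

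Epididymis and testis genes varied between libraries rather than with genotype. Of 19 listed genes, 5 were tested (median log2 fold change -0.98, mean 0.55, camera upward with adjusted p = 0.646). The genes named here were chosen after their values were seen, and their levels are CPM without TMM factors. The caput epididymis genes Gpx5 and Lcn8 reached 2811 and 1970 CPM in Srgn-knockout 3 and 238 and 269 CPM in wild-type 4, with at most 9.98 CPM in the others. Crisp1 and Rnase9 reached 846 and 103 CPM in Srgn-knockout 5, where Gpx5 was 0.111 CPM. The sperm protamine gene Prm2 had 215 CPM in wild-type 4, 64.6 CPM in wild-type 1 and 62.7 CPM in Srgn-knockout 5. Genes of the seminal vesicle stayed at or below 0.783 CPM. Without Srgn-knockout 3 and 5 and wild-type 4, Srgn was still the 1 gene past the threshold in edgeR, and the B-cell, T-cell and NK lists still passed in camera.

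The first principal component of the tested genes carried 37.3% of the variance and did not separate the genotypes (two-sided exact permutation p = 0.198). The second carried 16.8% and differed between them (p = 0.0317 by the same exact test). It also differed on the authors' values (exact p = 0.0159), but not when computed from the 500 most variable genes (exact p = 0.167). These p-values are not adjusted for the number of components tested. On the second component the groups overlapped. Wild-type 3 (13.1) lay above Srgn-knockout 1 (10.2), Srgn-knockout 2 (10.7) and Srgn-knockout 4 (7.52), while wild-type 1 (-45.5) and wild-type 2 (-22.7) were lowest. The test of this component was not repeated with single libraries left out.

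**Figure D4:**
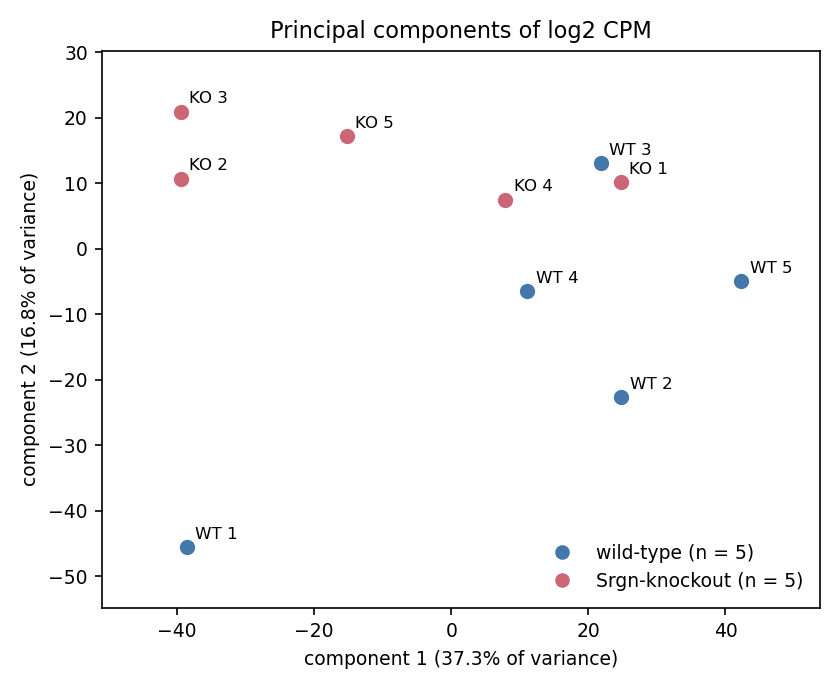
Scores of the 10 libraries on the first and second principal components of log2 CPM, with the percent of variance on each axis, wild-type in blue and Srgn-knockout in red. Wild-type 1 lies apart from the other wild-type libraries on both components.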

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

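The tests of the epididymis genes and of Mtrf1 were chosen after the values had been seen. For each named gene (log2 CPM), each list mean and the total count, the gap between the most extreme library of a group of 5 and its nearest neighbour was divided by the range of the group. The share was above the critical value of 0.71 in 21 of 228 groups; chance gives about 1 in 20, or 11.4, and neighbouring results share libraries.

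Among the list means, wild-type 1 lay below the other wild-type libraries for cholesterol synthesis (share of the range 0.901) and for extracellular matrix and fibrosis (0.835). Complement genes were highest in wild-type 3 (0.776). In Srgn-knockout, mast-cell genes were highest in Srgn-knockout 2 (0.804), endothelial genes lowest in Srgn-knockout 1 (0.792), and the neighbours of Srgn lowest in Srgn-knockout 5 (0.758).

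Among single genes in wild-type, H2-Ab1 (0.806) and Slamf9 (0.736) were lowest in wild-type 1, and Cxcl13 (0.798) was highest in wild-type 2. Hk1 (0.721) was highest in wild-type 4 and Tpsb2 (0.743) in wild-type 5, where Acaca (0.807), Mtrf1 (0.904) and Tdrd3 (0.739) were lowest. In Srgn-knockout, Aif1 (0.842) and Ciita (0.825) were highest and Rbp4 (0.773) was lowest in Srgn-knockout 1, while Cd2 (0.717) was highest and Prf1 (0.797) lowest in Srgn-knockout 2. Klrb1c (0.833) and Lcn2 (0.808) were highest in Srgn-knockout 3.

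Klrb1c and Lcn2, chosen after their values were seen, were highest in the library with the most caput epididymis RNA. Reads of epididymis tissue dissected with the fat are a candidate source of the epididymis genes: of a second list of epididymis genes, 12 of the 12 that reached 5 CPM in any library were highest in Srgn-knockout 3, Srgn-knockout 5 or wild-type 4. The highest library was Srgn-knockout 3 or Srgn-knockout 5 for each of these genes, so the count does not bear on wild-type 4. The most abundant of these genes were Defb20 at 899 CPM, Ly6g5b at 579 CPM and Adam28 at 303 CPM in Srgn-knockout 3. Carry-over from Srgn-knockout 3 into wild-type 4 stays open, since 15 genes stood there at a median of 11.5% of their level in Srgn-knockout 3, with a range of 7.44% to 14.8%, a ratio that adjoining tissue could give too. Carry-over at that share would not bring the sperm gene Prm2 to 215 CPM from the 42.2 CPM of Srgn-knockout 3, and no biological explanation was tested.

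Mtrf1, a mitochondrial translation release factor chosen after its values were seen, had 0 reads in wild-type 5 (up to 0.398 normalized CPM), and Srgn-knockout held 13.5 ± 1.07 normalized CPM. Too few reads in wild-type 5 is excluded, since 53.4 reads would be expected there at the level of the other wild-type libraries. A variant under the amplicon, carried in 0, 1 or 2 copies, may account for the pattern, as wild-type 1 to 4 stood at 49.97% of the Srgn-knockout mean (41.0% to 55.7%). A chromosome segment that differs between the animals stays open: of 61 tested genes within 10 Mb on chromosome 14, 1 followed Mtrf1 (1.64%, against 0.0743% elsewhere; Fisher's exact p = 0.0490), which is too few to decide. That gene was Tdrd3, at 21.5% of its Srgn-knockout mean in wild-type 5 and 44.6% to 62.0% in the other wild-type libraries. A difference in genetic background between the animals is therefore a possible explanation that these data do not settle. For both genes every wild-type library lay below every Srgn-knockout library. Such a difference would thus run along the groups and could not be told apart from the loss of Srgn.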

How the results depend on the processing

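The fit without the 3 libraries with the most epididymis RNA, the exact permutation test of list means and the use of members of at least 5 CPM alone were chosen after seeing the data. The Srgn log2 fold change was past the threshold and negative under every alternative, from -9.74 (without Srgn-knockout 5) to -7.89 when 1 library was left out and -6.35 on the authors' values, where the added 1 bounds it. Genes higher and lower numbered 114 and 107 by the DESeq2 Wald test (which gave no adjusted p for 25 genes), 2 and 8 by limma-voom with quality weights, 15 and 40 with 1 surrogate variable, and 0 and 3 with no low-count filter. Genes at an unadjusted p under 0.05 numbered 2653 with limma-voom, 540 without the 3 epididymis libraries (647 by chance) and 1118 to 2254 without 1 library. The cause was not tested; in the simulated data the DESeq2 test made 39 false calls among 190. Without 1 library, 0 genes were higher and 1 to 2 lower, with Rmrp added without wild-type 5 and Gemin8 added without Srgn-knockout 1. Klrb1c turned to lower values with limma-voom (log2 -0.92), on the authors' values (-0.27) and without the 3 epididymis libraries (-1.24), and ranged from -1.97 without Srgn-knockout 3 to 2.47. The authors' values moved Gemin8 (to -1.79), Cxcl13 (-1.06), Cd4 (-0.64), Cd8a (-1.01), Cd8b1 (-1.09), Cuzd1 (2.03) and Prom2 (1.85) by more than 1.5 times. Leaving out the 3 epididymis libraries did so for Srgn (-9.42), Fcmr (-2.76), Cd8b1 (-3.07), Cuzd1 (0.71), Pax8 (1.49), Prom2 (0.87) and Lcn2 (1.02), and the total count for Mtrf1 (1.91), Klrb1c (0.01), Lcn2 (1.25) and Cxcl13 (-1.20). Limma-voom moved Lcn2 to 1.02, and 1 surrogate variable moved Klrb1c to 0.53.

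Lists lower numbered 7 with library size alone, with limma-voom and on the authors' values, 6 with upper-quartile factors and with no filter, 3 with the stricter filter and with members of at least 5 CPM, 2 with 1 surrogate variable, 1 with fry, and 0 with the estimated correlation and with the exact permutation test. Library size alone moved the median of all genes to 0.05 on the log2 scale. Dendritic cells and MHC class II became lower with upper-quartile factors (adjusted p = 0.0284), library size alone (0.0213), limma-voom (0.00219), no filter (0.0362), the stricter filter (0.0454), the authors' values (0.0237), members of at least 5 CPM (0.0394), without wild-type 1 (0.00193) and without Srgn-knockout 1 (0.0229). Inflammatory cytokines did so in the first 4 of these (0.0427, 0.0243, 0.00760 and 0.0286), on the authors' values (0.0269), without wild-type 1 (0.00210) and without Srgn-knockout 1 (0.0229). Lipid-associated macrophages did so with library size alone (0.0404), limma-voom (0.00409), the authors' values (0.0408), the total count (0.00712), without wild-type 1 (9.00e-05) and without Srgn-knockout 1 (0.0316). Immediate early and stress genes did so with the total count (0.0190), without wild-type 1 (0.0452) and without wild-type 2 (0.0465). Endothelial cells became higher with limma-voom (0.000483), no filter (0.0267), the stricter filter (0.0454), without wild-type 1 (0.00203) and without Srgn-knockout 1 (0.00112), and the cell cycle with 1 surrogate variable (0.000739). The T-cell and NK lists had too few members for a test with the stricter filter (3 and 2) and with members of at least 5 CPM (4 each), where B cells had 0.00196 and 0.00185 and macrophages 0.0235 and 0.0201. Without 1 library, 2 to 10 lists were lower and 0 to 3 higher: 10 and 1 without wild-type 1, among them the interferon response (0.0336) and the cell cycle (0.0302) as lower, 7 and 3 without Srgn-knockout 1, with fatty acid synthesis (0.0316) and thermogenic genes (0.0480) as higher, and 2 and 0 without wild-type 3. For macrophages the adjusted p was 0.0505 with 1 surrogate variable, 0.230 without the 3 epididymis libraries, 0.898 with the estimated correlation, 0.769 with fry and 0.762 by exact permutation. With these 3 set tests it was 0.838, 0.304 and 0.381 for T cells and 0.897, 0.408 and 0.508 for NK genes, which had 0.0505 with 1 surrogate variable. For B cells it was 0.0911 with the estimated correlation and 0.254 by exact permutation. With 1 library left out it ranged from 7.35e-09 to 0.000108 for B cells, 5.39e-09 to 0.0011 for T cells, 6.70e-06 (without wild-type 1) to 0.143 (without wild-type 5) for macrophages and 0.00187 to 0.103 (without wild-type 3) for NK genes.

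Lists that had not passed changed sign as follows, and the cause was not tested. Neutrophils turned upward with no filter (adjusted p = 0.904), the total count as covariate (0.890), 1 surrogate variable (0.871), without the 3 epididymis libraries (0.534) and with fry (0.978). The cell cycle turned upward with no filter (0.904), with the stricter filter (0.942), with 1 surrogate variable (0.000739, past the threshold), without the 3 epididymis libraries (0.373), with fry (0.999) and by exact permutation (0.984). With 1 surrogate variable, adipocytes (0.725), blood (0.976) and the circadian clock (0.592) reversed; with the total count, fatty acid oxidation (0.809), blood (0.844) and the circadian clock (0.935) did. Limma-voom turned cholesterol synthesis and extracellular matrix (0.753 each). Leaving out the 3 epididymis libraries turned proteoglycans (0.799), blood (0.723) and the circadian clock (0.826). Leaving out 1 library turned the sign of further lists at least once, with adjusted p from 0.178 to 0.928 for adipocytes, 0.336 to 0.987 for blood, 0.0302 (without wild-type 1, sign kept) to 0.942 for the cell cycle, 0.285 to 0.952 for cholesterol synthesis and 0.325 to 0.982 for the circadian clock. The same held for epididymis and testis (0.120 to 0.920), extracellular matrix (0.285 to 0.978), fatty acid oxidation (0.313 to 0.947), mesothelial cells (0.213 to 0.928), neutrophils (0.557 to 0.983) and oxidative phosphorylation (0.313 to 0.974). The exact permutation p of the second component was 0.167 with the 500 most variable genes and 0.0159 on the authors' values. No paired analysis was possible because the labels pair no animals. The median SE was 0.165. In simulated data edgeR recovered 64.2% of genes changed 2-fold, but the simulation gave genes no shared variation. That share is therefore no measure of what edgeR could detect in these libraries. Here 362 tested genes had an absolute log2 fold change of at least 1, and of these only Srgn passed in edgeR. How many of them truly differ is not known. Small changes were often not detectable at this depth and number of animals, and changes of 2-fold or more may have been missed too.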

Other observations

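The correlations between lists and the tests of the B-cell and T-cell lists were chosen after the values had been seen, while the counts over other splits of the libraries were planned. Macrophage RNA in the fat differed widely between animals of the same genotype. The list mean of lipid-associated macrophage genes ran from -1.36 in wild-type 1 to 1.29 in wild-type 5, and the genotypes accounted for 4.58% of its variance, against 75.6% for B cells, 50.1% for T cells, 39.4% for NK genes and 11.96% for macrophages. The share was not particular to lymphocytes: skeletal and smooth muscle genes, which had higher values in Srgn-knockout and did not pass, had 50.7%. Any grouping of the libraries accounts for some variance. In the exact permutation test the macrophage list had p = 0.325, and 0 of the 32 lists passed after adjustment. Libraries with more lipid-associated macrophage RNA had less adipocyte RNA (Pearson r = -0.898, permutation p = 0.00047, adjusted p = 0.000705; Spearman rho = -0.891, permutation p = 0.00121, adjusted p = 0.00181; r = -0.804 without wild-type 1 and wild-type 5). They also had more cell cycle RNA (r = 0.933, permutation p = 7e-05, adjusted p = 0.00021; rho = 0.964, permutation p = 4e-05, adjusted p = 0.00012; r = 0.914 without the same libraries). The relation with B-cell genes was not detectable (r = 0.215, permutation p = 0.548; rho = 0.127, permutation p = 0.734, both unchanged by adjustment; r = 0.153 without the same libraries). These 3 relations pool 10 libraries of both genotypes. The adjusted p-values cover these 3 relations alone and do not correct for their choice among all pairs of lists. CPM values are shares of a total, so a larger share of macrophage RNA can by itself lower the share of adipocyte genes. With each list mean centred within its genotype and permuted within it, the relation with adipocyte genes was r = -0.894 (permutation p = 0.00057, adjusted p = 0.000855; rho = -0.903, permutation p = 0.00237, adjusted p = 0.00355; r = -0.780 without the same libraries). That with cell cycle genes was r = 0.960 (permutation p = 0.0001, adjusted p = 0.0003; rho = 0.964, permutation p = 9e-05, adjusted p = 0.00027; r = 0.926 without them). That with B-cell genes was r = 0.0599 (permutation p = 0.912; rho = -0.0182, permutation p = 0.976, both unchanged by adjustment; r = -0.471 without them). Gpr50, chosen after its values were seen, ran from 1.27 CPM in wild-type 1 to 203 CPM in wild-type 5 (without TMM factors).

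The noncoding RNA genes Snora16a, Snord15a and Rpph1 were chosen after their values were seen, and none passed the threshold. Noncoding RNAs were not tested as a group, and Ctcflos had a higher value (log2 0.58). Snora16a had 311 ± 62.6 CPM in wild-type and 199.5 ± 22.1 CPM in Srgn-knockout, and Snord15a 307 ± 39.6 and 215 ± 23.5 CPM (edgeR adjusted p = 0.191 for both). Rpph1, the RNA of RNase P, had 9408 ± 839 and 8279 ± 583 CPM (edgeR adjusted p = 0.502). The epithelial genes Cuzd1, Prom2 and Pax8 were also chosen after their values were seen, and none passed the threshold (edgeR adjusted p = 0.284, 0.276 and 0.220). High in single Srgn-knockout libraries were Cuzd1, at 377 and 151 normalized CPM in Srgn-knockout 5 and 3 and at most 37.9 CPM elsewhere, Prom2, at 75.2 and 28.9 CPM there, and Pax8, at 26.7 CPM in Srgn-knockout 3 and 16.1 CPM in Srgn-knockout 5. Without Srgn-knockout 5 the log2 fold change of Cuzd1 went from 3.09 to 1.93 and that of Prom2 from 3.23 to 2.0. Srgn-knockout 3 and 5 were among the 3 libraries with the most epididymis RNA.

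The lower levels of B-cell and T-cell genes in Srgn-knockout were weighed against depth, single libraries and a general loss of immune cells. Depth is excluded as the whole cause, since after thinning all libraries to the smallest total the list means still differed by -0.74 for B cells (SE 0.137) and -0.80 for T cells (SE 0.284), against -0.73 and -0.81 before. A single wild-type library rich in lymphocytes is excluded for B cells, whose difference closest to 0 was -0.64 without wild-type 2 (SE 0.135), and stays open for T cells, which had -0.59 without wild-type 3 (SE 0.217). A lower share of all immune cells cannot be told apart from a loss of lymphocytes in particular, because macrophage levels varied widely: relative to the macrophage list the exact permutation p was 0.381 for B cells and 0.254 for T cells. An effect of the genotype on lymphocytes in fat stays open as well and was not tested beyond the comparison itself.

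Splits of the 10 libraries into other groups of 5 gave a reference for these counts. Of 126 possible splits, 100 were drawn, the real one included. The 1 gene past the threshold in edgeR was Srgn, the deleted gene that defines the groups, so the 4 of 100 splits with as many genes (highest other 993) say nothing about chance for other genes. For the 1632 genes at an unadjusted p under 0.05 chance cannot be excluded (8 of 100 splits; highest other 3530), nor for the 221 genes of DESeq2 (5 of 100; highest other 1884), nor for the 4 lists of camera with the preset correlation (79 of 100; highest other 22). Camera with the preset correlation called a median of 8 lists in the other splits. The split with 993 genes differed from the genotypes by exchanging wild-type 1 and Srgn-knockout 1, and Srgn itself had an edgeR adjusted p of 0.345 in it. The exchange leaves the other libraries on their genotype side, so this split is not free of genotype. It also sorted the libraries by macrophage list mean. Wild-type 1 and Srgn-knockout 2 to 5 ran from -0.84 to 0.17, and the other libraries from 0.21 to 0.79. The lipid-associated macrophage list was not sorted so, with 0.01 in wild-type 2 and 0.42 in Srgn-knockout 4. This was seen after the split was known. Macrophage content as the source of the 993 genes was not tested, and the labels name no source.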
